A study of Mus musculus with 6 samples.

How the data were processed

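Lung total RNA of 3 mouse genotypes was hybridised to 6 arrays, 2 per genotype, and each array was deposited as a scanner file together with a set of values for the whole series. Per the labels' protocols, RNA was extracted from the lungs with a column kit and cRNA was labelled with the single dye Cy3. Per the file headers, the intensity values were extracted with Agilent Feature Extraction 9.5.3.1, a single-colour protocol and a 44K mouse design whose grid was built on mm7, while the submitters' processing notes name Feature Extraction 9.1; which of these versions produced the deposited intensity values stays open. Per the file headers and the values, the processed signal is a linear intensity, background-subtracted and detrended within the array and not yet scaled between arrays. The deposited series table holds, for all 45018 features of every array, the background-subtracted intensity of the scanner files (relative tolerance 1e-04), on a linear scale, uncentred and unscaled between arrays, with medians of 88.2 and 86.8 for WT, 115 and 87.0 for tg/wt and 74.4 and 92.2 for tg/tg; it was used as an alternative source.

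The main values were log2 of the processed intensity minus each array's 75th percentile of it. Of 45018 spots per array 43379 were not controls, which make up 41174 probes, 245 of them printed in 10 spots and averaged. Spots with an outlier mark, 138 to 187 per array, and control spots were left out, and saturated spots, 3 per array, were kept. Of the probes 22951 were matched by accession to 16358 gene symbols of a reference gene set on assembly GRCm38, and 18223 had no symbol there and are not named. Because that assembly differs from the design's, no coordinates are given. Probes entered if well above background on at least 2 of the 6 arrays (27514 probes, 18212 with a symbol), 20 probes with a missing spot were left out, and each gene was represented by the probe with the highest mean over all arrays, which gave 12968 genes. Where a gene was not well above background on any array of a group, its fold is a bound: the brighter group's mean over the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Array number limits the precision, and the 75th percentiles of 794 to 1204 intensity units show how far the arrays differ in brightness.

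Groups were taken from the genotype labels. All 6 arrays entered a single linear model of group means in limma 3.58.1 (lmFit and eBayes, R 4.3.3, data.table, version 1.17.8), which left 3 residual degrees of freedom and a prior of 1.77, and p-values were adjusted by Benjamini-Hochberg over all genes with a threshold of 0.05. Gene lists for lung, T cells, alveolar proteinosis and other cell types or tissues a lung sample can hold, 28 of which had at least 5 tested members, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 28 lists; camera with an estimated correlation and fry were alternatives. Simulated unchanged groups gave the values for comparisons that share the WT arrays. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

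Design, lists, tests, alternatives and the rule for named genes were fixed before the data were examined, apart from the items stated here to be later. The rule names Tbx21 first. It then names the 10 genes with the largest rise and the 10 with the largest fall in tg/tg against WT, and 5 and 5 in the other comparisons, among genes past the threshold whose groups' arrays do not overlap, that are well above background on every array of the higher group and that carry a regular gene symbol. From each list it names up to 4 members past the threshold with the largest change, or the member with the smallest p where none passed, and sex-linked genes are given per array. List members outside the rule are named only where they went against their list. A normexp correction on the mean signal had been planned; the files used here hold no such column, so normexp with offset 50 on the median signal took its place after the data were seen. Local backgrounds of up to 21737.5 units on WT 1 and 979.5 on WT 2, against medians of 58 and 59, distorted that fit: the lowest 1% of WT 1 came out at 9.37 on the log2 scale, and WT 1 and WT 2 correlated at 0.969. A second version with local backgrounds that carry an outlier mark or exceed 2 times the array's median set to that median, also added after the data were seen, gave a correlation of 0.998. Other alternatives were quantile normalization, scaling to the median of probes well above background on all arrays, no filter or a stricter filter on dim probes, a floor on low values, the mean of a gene's probes, every probe on its own, variance moderation with an intensity trend, fits of only the groups compared, the series values, slide or replicate number as a block, and leaving out each array.

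The fit was tested on simulated data for the comparison of tg/tg with WT over 12968 genes, with 50 genes changed per size: 6% were recovered at a log2 change of 0.25, 46% at 0.5, 82% at 1 and 98% at 2, and 11 unchanged genes were called. The slope of fitted on true changes was 0.994, a shifted list was found (adjusted p = 6.27e-47) with 0 other lists called, and 0 genes were called in a simulated comparison without changes. For the list test, genes were drawn independently and only the shifted list was changed. It therefore does not measure false list calls in the real data, where genes can move together and most genes differ. The recovery rates for single genes do not carry over either. Few genes were changed in the simulation, while 74.7% passed in the real comparison of tg/tg with WT. Replicates were compared over 179 probes printed in several spots: their trimmed mean squared difference was 2.99 times the spot noise in WT, 9.28 times in tg/wt and 11.2 times in tg/tg, and 154 to 3014 times between groups. The chi-square test on the untrimmed sum gave p = 1.29e-64 in WT. A further 9302 tested probes without a symbol were not used in gene counts; of these 2988 were higher and 3143 lower in tg/tg against WT, 1033 and 837 in tg/wt against WT, and 2773 and 3273 in tg/tg against tg/wt. The Th17 and thymus lists had 3 tested members each and were not set-tested. The result for a member of the Th17 list is not reported.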

Results

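Total RNA from the lungs of C57BL/6 mice was measured on 6 single-colour (Cy3) Agilent mouse arrays, 2 for each of 3 genotypes: WT, and the genotypes labelled tg/wt and tg/tg for the hCD2-T-bet transgene. T-bet, encoded by Tbx21, is the transcription factor that directs the T helper 1 (Th1) programme, and the transgene overexpresses it in T cells. The series asks which lung genes differ in these mice, in connection with pulmonary alveolar proteinosis, a disease in which surfactant material fills the air spaces. The 75th percentile of the signal lay between 794 and 1204 intensity units per array, the median signal between 76.7 and 118, and 62.0% to 66.8% of probes were well above background. The probe for Sftpc, which encodes surfactant protein C, was saturated on all 6 arrays and gives no fold. With 2 arrays per group, the number of arrays limits the precision. The 4 WT and tg/tg arrays lay on slide 1 (scan 1) and the 2 tg/wt arrays on slide 2 (scan 2). In both comparisons that involve tg/wt the slide and the group cannot be told apart.

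Replicate arrays of a group correlated at r = 0.997 in WT, 0.997 in tg/wt and 0.996 in tg/tg across genes, which are not independent replicates. WT and tg/wt arrays correlated at 0.990 to 0.991, and tg/tg arrays with the others at 0.921 to 0.933. Replicates differed by more than the noise between spots of one probe and were counted as separate samples. The labels do not state that they came from separate animals, so the p-values measure the spread between these arrays, which may be technical. The Y-linked genes Eif2s3y, Ddx3y and Kdm5d were measured in every group. The other sex-linked genes listed, Uty and Xist, were on the array but did not meet the rule for tested probes. On WT 1, WT 2, tg/wt 1, tg/wt 2, tg/tg 1 and tg/tg 2 the log2 level of Eif2s3y was 1.65, 1.55, 0.96, 0.87, 1.91 and 2.04. The level of Ddx3y on the same arrays was 0.52, 0.57, 0.11, 0.15, 0.45 and 0.40. For Kdm5d it was -2.61, -2.62, -2.75, -2.80, -2.79 and -2.83. Eif2s3y and Ddx3y were lowest on the tg/wt arrays.

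Tbx21 rose with the transgene in every array. Its log2 signal relative to each array's 75th percentile was -0.70 and -0.71 in WT, 1.30 and 1.34 in tg/wt, and 3.25 and 3.26 in tg/tg. The level was 4.07-fold higher in tg/wt than in WT (log2 difference 2.02, SE 0.0339, limma adjusted p = 1.05e-04) and 15.6-fold higher in tg/tg than in WT (3.96, adjusted p = 6.38e-07). It was 3.83-fold higher in tg/tg than in tg/wt (1.94, adjusted p = 2.83e-06). A single probe measures Tbx21, and how far it sees the transgene's transcript in addition to the endogenous one is not known here.

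**Figure D1:**
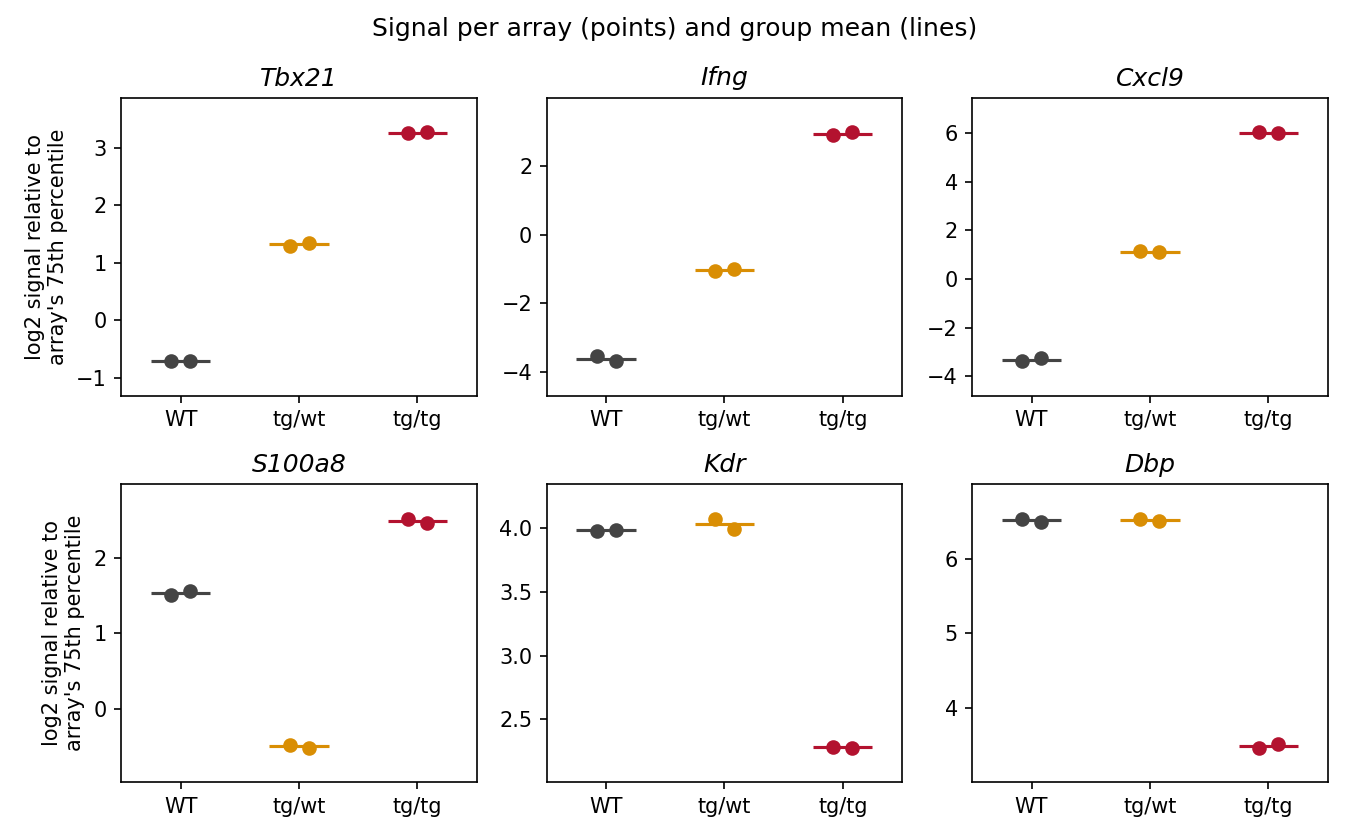
Log2 signal relative to each array's 75th percentile for 6 genes, with points for the 2 arrays of each genotype and lines for the group mean; each panel has its own vertical scale and does not start at 0. Tbx21, Ifng and Cxcl9 step up from WT to tg/wt to tg/tg, S100a8 is lowest in tg/wt, and Kdr and Dbp are lowest in tg/tg.

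The comparison of tg/tg with WT asks how the lung of the genotype with the highest Tbx21 differs from normal lung. Interferon-gamma response genes, inflammatory chemokines, T cell genes and monocyte and interstitial macrophage genes were higher in tg/tg, while genes of heart muscle, fat, endothelium, airway epithelium and the clock output were lower. None of these lists passes with the correlation between genes estimated, where the smallest is adjusted p = 0.0662 with an estimated correlation. The estimate lay below the preset 0.01 for the interferon-gamma (-0.0252), inflammatory chemokine (-0.0129) and clock output (-0.0376) lists. A higher correlation between genes is therefore not why these calls ended. For the other lists named it lay above 0.01, up to 0.411 in fat. The endothelial list, at 0.018, had the same adjusted p = 0.0678 with an estimated correlation as the clock output list. A call that ends with the estimate therefore does not show that a list's genes move together. The largest rises were in Ubd, which encodes the ubiquitin-like protein FAT10 (log2 difference 10.87, SE 0.0451, 1876-fold), the acute-phase gene Saa3 (9.38, SE 0.0540, 666-fold) and Cxcl9, an interferon-gamma-induced chemokine (9.35, SE 0.0504, 653-fold). Among the largest falls were the amino acid transporter gene Slc7a10 (at least 150-fold lower), the fatty acid binding protein gene Fabp1 (at least 90.1-fold lower) and Cidec, a lipid droplet gene (log2 difference -6.43, SE 0.0439, 86.3-fold lower). Of 12968 genes tested, 4388 were higher and 5297 lower in tg/tg, or 74.7% in all (limma, Benjamini-Hochberg threshold 0.05).

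The remaining genes with the largest rises by fitted difference were Gzmk, a granule protease of cytotoxic lymphocytes (at least 78.5-fold), the neutrophil-attracting chemokine genes Cxcl5 (at least 52.6-fold) and Cxcl3 (at least 39.7-fold), Gpr84 (at least 68.5-fold), the neuropeptide gene Npy (at least 48.1-fold), Cxcl10 (151-fold) and the acute-phase gene Saa1 (137-fold). The remaining largest falls were in Nppa, the atrial natriuretic peptide gene (83.8-fold), Bex2 (82.3-fold), Mb, which encodes myoglobin (66.3-fold), Cst8 (58.4-fold, with 1 of 2 tg/tg arrays well above background), Pck1, an enzyme of gluconeogenesis (at least 23.3-fold), and the cytochrome P450 genes Cyp2e1 (at least 19.1-fold) and Cyp1a1 (at least 16.4-fold). Adjusted p-values of these 20 genes lay between 6.38e-07 and 3.49e-05. A fold given as "at least" stands where the gene was not well above background on either array of the lower group.

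Among lists fixed before the data were examined, all 23 tested interferon-gamma response genes rose in tg/tg (median log2 difference 4.10, and 4.02 with genes below background at their bound). The camera adjusted p was 1.36e-12, and adjusted p = 0.0662 with an estimated correlation. Examples are Cxcl9, Gbp6 (27.8-fold), a guanylate-binding protein gene, and Nos2 (at least 7.35-fold), the inducible nitric oxide synthase. Of 19 Th1 and T-bet target genes 18 rose and Hopx fell by 1.57 (median 3.30, adjusted p = 2.52e-08, and adjusted p = 0.0662 with an estimated correlation). The 18 include Tbx21 itself, which encodes the transgene's product and was not taken out of the list test. Ifng itself was 95.1-fold higher (log2 difference 6.57, SE 0.0648), Ccl3 112-fold, Ccl4 75.2-fold and Ccl5 25.7-fold. All 17 type I interferon response genes rose (median 2.60, adjusted p = 8.67e-09, and adjusted p = 0.0678 with an estimated correlation), among them Oas3 (36.0-fold), Zbp1 (24.6-fold) and Irf7 (11.2-fold). Of 20 inflammatory cytokine and chemokine genes 18 rose, with Ccl2 81.5-fold, Ccl8 74.1-fold and Tnf 48.0-fold higher, while Ccl17 fell by 3.75 and Il18 by 0.18 (median 4.50, or 3.98 with bounds, adjusted p = 5.19e-08, and adjusted p = 0.0662 with an estimated correlation). Of 11 genes of MHC class II presentation 10 rose, including Ctss (10.9-fold), Ciita (5.74-fold) and H2-Aa (4.99-fold), and H2-Ob fell by 0.71 (median 2.02, adjusted p = 3.72e-05, and adjusted p = 0.0860 with an estimated correlation). For these lists the counts adjusted over the list alone were the same.

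T cell genes rose in 19 of 21 cases, led by Cd6 (18.0-fold), Icos (17.7-fold) and Cd5 (11.7-fold), and 2 fell: Ccr7 by 1.61 and Tcf7 by 0.38 (median 2.44, or 2.24 with bounds, adjusted p = 1.29e-07, and adjusted p = 0.0685 with an estimated correlation). Of 13 NK and cytotoxic genes 11 rose, among them Nkg7 (18.4-fold) and Il2rb (9.49-fold), and Ncr1, a receptor of NK cells, fell by 0.98 (median 1.18, adjusted p = 5.48e-05, and adjusted p = 0.0678 with an estimated correlation). Neutrophil genes rose in 13 of 14 cases, with Lcn2 30.0-fold, Mpo 12.3-fold and Cd177 9.73-fold higher (median 1.07, adjusted p = 5.48e-05, and adjusted p = 0.116 with an estimated correlation). Of 17 proliferation genes 16 rose, including Ccnb1 (6.27-fold), Aurkb (4.69-fold) and Cdk1 (4.48-fold), with a median of 1.92, or 1.82 with bounds (adjusted p = 1.28e-07, and adjusted p = 0.0678 with an estimated correlation). B cell and plasma cell genes went both ways, 8 of 16 higher, led by Cd72 (12.0-fold) and Fcer2a (6.87-fold), and 6 lower (median 0.21, adjusted p = 0.350). Th2 genes also divided: Il10 (at least 5.31-fold) and Il24 (6.56-fold) rose, and Gata3 (2.06-fold), Il4 and Il1rl1 (log2 difference -0.46) fell (median -0.14, or -0.06 with bounds, mean 0.57, adjusted p = 0.912). The call of Il4 (at least 1.04-fold) ended with both normexp versions, the floor on low values and the series values. Of 7 eosinophil and mast cell genes 5 rose, with Epx at least 1.69-fold higher, and Kit fell 2.56-fold (median 0.67, adjusted p = 0.0895). The Th17 list had too few members for a set test: Ccl20 was 2.81-fold higher and Ccr6 1.48-fold lower. The counts adjusted over the list alone were the same for these lists, except that 6 eosinophil and mast cell genes were then higher.

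Monocyte and interstitial macrophage genes rose in 16 of 18 cases (17 adjusted over the list alone), with Ms4a7 30.3-fold, Fcgr1 22.4-fold, Gpnmb 22.1-fold and the complement gene C1qb 16.7-fold higher (median 3.15, adjusted p = 1.82e-08, and adjusted p = 0.0678 with an estimated correlation). Of 16 alveolar macrophage genes 6 rose and 10 fell (median -0.73, adjusted p = 0.350), with the same counts adjusted over the list alone. Cidec, Fabp1, Krt79 (29.7-fold) and the ribonuclease gene Ear1 (log2 difference -3.33) fell furthest. Genes of lysosomes and proteases rose in 17 of 18 cases, the same adjusted over the list alone. Mmp12 was 59.1-fold higher, with 1 of 2 WT arrays well above background, Acp5 6.74-fold and Ctsk 6.09-fold (median 1.66, adjusted p = 1.29e-07, and adjusted p = 0.0662 with an estimated correlation). Of 19 genes of macrophage lipid handling 9 rose (10 adjusted over the list alone) and 6 fell (median 0.30, adjusted p = 0.166). The scavenger receptor genes Msr1 (60.7-fold) and Olr1 (8.07-fold) and Apoe (3.39-fold) were higher, and Cidec was lower. In the GM-CSF axis, the signalling route that alveolar macrophages need to clear surfactant, 7 of 10 genes rose and 2 fell (median 1.37, adjusted p = 0.0156, and adjusted p = 0.155 with an estimated correlation). The receptor genes Csf2rb2 (13.0-fold) and Csf2ra (3.78-fold), Spi1 (5.77-fold) and Csf2 itself (2.99-fold) were higher, and Pparg fell by 0.96 and Stat5b by 0.30.

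Surfactant and alveolar type 2 genes did not move together: 6 of 17 rose and 5 fell (median -0.00, mean 0.16, adjusted p = 0.546), and the same counts hold among the 16 without the saturated Sftpc (adjusted p = 0.560). Ctsh (2.78-fold), Sftpd, which encodes surfactant protein D (1.88-fold, log2 difference 0.91, SE 0.0471), and the desaturase gene Scd1 (1.84-fold) were higher, and Lgi3 was 1.92-fold lower. Of 7 alveolar type 1 genes Pdpn was 2.29-fold higher and 5 were lower, including Cyp2b10 (3.12-fold) and Cav1 (2.38-fold) (median -0.33, adjusted p = 0.233). All 13 airway epithelium genes fell, among them Bpifa1 (18.2-fold), Tppp3 (4.60-fold) and the club cell gene Cyp2f2 (3.95-fold), with a median of -1.54 (adjusted p = 3.67e-05, and adjusted p = 0.116 with an estimated correlation). All 16 endothelial genes fell (median -1.31, adjusted p = 6.02e-06, and adjusted p = 0.0678 with an estimated correlation), including the receptor genes Tek (3.31-fold) and Kdr (3.25-fold). Fibroblast and matrix genes went both ways, 10 of 18 higher, led by the protease inhibitor gene Timp1 (20.1-fold) and Tnc (4.54-fold), and 8 lower, led by Lum (2.64-fold) (median 0.57, adjusted p = 0.270). The counts adjusted over the list alone were the same for all of these lists.

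The heart muscle, fat, skeletal muscle and erythroid lists, for other tissues that a lung sample can hold, were lower in tg/tg. All 9 heart muscle genes fell (median -3.93, adjusted p = 8.67e-06, and adjusted p = 0.106 with an estimated correlation), with Nppa, Myl7 (22.6-fold) and Sln (22.3-fold) in front. All 6 fat genes fell (median -4.19, or -3.27 with bounds, adjusted p = 0.00140, and adjusted p = 0.212 with an estimated correlation), among them the adipokine gene Adipoq (54.9-fold, 1 of 2 tg/tg arrays well above background) and Cfd (54.5-fold). Of 7 skeletal muscle genes 6 fell, including Ckm (at least 29.3-fold) and Myh4 (15.9-fold), with a median of -1.48 (adjusted p = 0.00420, and adjusted p = 0.106 with an estimated correlation). All 5 erythroid genes fell, with Slc4a1 2.14-fold and Alas2 1.82-fold lower (median -0.85, adjusted p = 0.0428, and adjusted p = 0.175 with an estimated correlation). All 10 clock output genes fell (median -1.65, adjusted p = 9.68e-05, and adjusted p = 0.0678 with an estimated correlation), among them Dbp (8.13-fold, log2 difference -3.02, SE 0.0373), Ciart (4.81-fold) and Hlf (4.76-fold). Immediate early and heat shock genes went both ways, 5 of 13 higher, including Junb (2.23-fold), and 6 lower, including Nr4a1 (2.81-fold) (median -0.13, adjusted p = 0.982). The thymus list had too few members for a set test: Cd1d1 (2.43-fold) and Dntt (1.89-fold) were higher and Ccl25 (1.63-fold) lower. The counts adjusted over the list alone were the same for all of these lists.

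Within slide 1, where both groups lie, which is also the fit with slide as a block, 4321 genes were higher and 5183 lower, and the same 12 lists were called higher and 7 lower as in the fit of all arrays in tg/tg vs WT. A normexp background correction on the median signal left 1779 genes higher and 2342 lower, and the erythroid call ended with it (adjusted p = 0.201) and without WT 1 (0.0508), WT 2 (0.0539) or tg/tg 1 (0.0522).

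The comparison of tg/wt with WT asks how the lung differs at the intermediate Tbx21 level. Th1, interferon-gamma response, T cell, NK and cytotoxic, B cell and proliferation genes were higher in tg/wt, and neutrophil, heart muscle and airway genes were lower. None of these lists passes with the correlation estimated, where the smallest is adjusted p = 0.0513 with an estimated correlation. Cxcl9 was 21.9-fold higher (log2 difference 4.45, SE 0.0504), Gzmk at least 4.99-fold and Ifng 6.05-fold (2.60, SE 0.0648). Clca1, a gene of mucus-producing airway cells, was 32.2-fold lower (log2 difference -5.01, SE 0.0530), the eosinophil granule protein gene Prg2 6.66-fold and the neutrophil gene S100a8 4.09-fold (-2.03, SE 0.0402). Of the 12968 genes, 1732 were higher and 1887 lower, or 27.9% (limma, Benjamini-Hochberg threshold 0.05).

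By fitted difference, the other genes with the largest rises were Atcay (at least 12.6-fold), Fbxw14 (at least 4.69-fold) and Mageb4 (at least 2.75-fold). Those with the largest falls were Acsbg2 (at least 4.56-fold), Vwa7 (at least 3.80-fold), Pabpc5 (at least 3.03-fold) and Oog1 (at least 2.07-fold). All 7 were not well above background on either array of the lower group, and their adjusted p-values lay between 2.91e-04 and 0.0242. Their rank rests on fitted values below background. Genes measured in both groups, such as Cxcl10 (6.43-fold higher) and Nppa (log2 difference -2.36), moved further than most of these bounds. Without tg/wt 1 the calls of Acsbg2, Pabpc5 and Oog1 ended, and without tg/wt 2 those of Fbxw14, Pabpc5 and Oog1.

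Of 19 Th1 and T-bet target genes 16 rose in tg/wt (17 adjusted over the list alone) and Il18r1 fell by 0.55 (median 1.07, camera adjusted p = 2.41e-11, and adjusted p = 0.0513 with an estimated correlation). Tbx21 itself is among the 16. Ccl4 was 4.15-fold and Ccl3 3.55-fold higher. Interferon-gamma response genes rose in 22 of 23 cases, with Cxcl10 6.43-fold, Gbp6 2.28-fold and Igtp 2.11-fold higher (median 0.74, adjusted p = 9.29e-17, and adjusted p = 0.0513 with an estimated correlation). The remaining member, Nos2, had a log2 difference of 0.50 that did not pass. All 11 MHC class II genes rose, including H2-Oa (1.81-fold), H2-Eb1 (1.70-fold) and H2-Ob (1.64-fold), with a median of 0.64 (adjusted p = 1.52e-08, and adjusted p = 0.0659 with an estimated correlation). Of 21 T cell genes 17 rose (19 adjusted over the list alone), led by Cd6 (2.61-fold) and Lck (2.59-fold), with a median of 0.65 (adjusted p = 1.16e-12, and adjusted p = 0.0554 with an estimated correlation). NK and cytotoxic genes rose in 12 of 13 cases, among them Nkg7 (3.07-fold) and Prf1 (2.12-fold), with a median of 1.04 (adjusted p = 3.95e-10, and adjusted p = 0.0513 with an estimated correlation). Of 16 B cell and plasma cell genes 14 rose, including Cd72 (2.75-fold) and Spib (2.17-fold), and Jchain, the joining chain gene of secreted antibodies, fell by 0.93 (median 0.83, adjusted p = 1.17e-08, and adjusted p = 0.0513 with an estimated correlation). Proliferation genes rose in 15 of 17 cases, with Ccnb1 1.99-fold and Aurkb 1.91-fold higher (median 0.74, adjusted p = 9.57e-11, and adjusted p = 0.0513 with an estimated correlation). Of 17 type I interferon genes 7 rose (10 adjusted over the list alone), including Zbp1 (2.16-fold), and Rsad2 fell by 0.33 (median 0.15, adjusted p = 0.00165, and adjusted p = 0.178 with an estimated correlation). Where no other count is given, the counts adjusted over the list alone were the same.

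Neutrophil genes fell in 13 of 14 cases in tg/wt, with S100a8, Cxcr2 (4.06-fold) and S100a9 (3.88-fold) lowest (median -1.63, or -1.44 with bounds, adjusted p = 8.52e-10, and adjusted p = 0.0757 with an estimated correlation). Lcn2 had a log2 difference of 0.15 that passed only when adjusted over the list alone. Inflammatory cytokine and chemokine genes did not pass as a list, with 8 of 20 higher, such as Ccl8 (3.61-fold) and Tnf (2.58-fold), and 4 lower, such as Il1b (1.95-fold), or 9 and 5 adjusted over the list alone (median 0.19, adjusted p = 0.0524). Monocyte and interstitial macrophage genes rose in 11 of 18 cases, including Ms4a7 (2.47-fold) and C1qb (1.74-fold), and Spp1 fell by 0.68 and Cd14 by 0.16 (median 0.25, adjusted p = 8.67e-05, and adjusted p = 0.0954 with an estimated correlation). Alveolar macrophage genes went both ways, 6 of 16 higher, such as Ear1 (1.40-fold), and 3 lower, or 8 and 4 adjusted over the list alone (median 0.16, adjusted p = 0.370). Of 18 lysosome and protease genes only Acp5 rose (1.21-fold) and only Mmp12 fell, by at least 1.02-fold with 1 of 2 WT arrays well above background, and leaving out tg/wt 2 ended both calls (median 0.03, adjusted p = 0.572). Of 19 lipid handling genes 2 rose, including Olr1 (1.36-fold), and 5 fell, including Fabp4 (1.60-fold) (median -0.02, adjusted p = 0.767). In the GM-CSF axis 5 of 10 genes rose, with Csf2 1.54-fold and Csf2rb2 1.35-fold higher (median 0.22, adjusted p = 0.00997, and adjusted p = 0.178 with an estimated correlation). Of 7 eosinophil and mast cell genes Cma1 rose 1.47-fold and Prg2 and Mcpt4 (1.40-fold) fell (median 0.15, mean -0.26, adjusted p = 0.9985), and 2 rose adjusted over the list alone.

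Surfactant and alveolar type 2 genes rose in 8 of 17 cases (9 adjusted over the list alone), among them Etv5 (1.36-fold), Slc34a2 (1.26-fold) and Muc1 (1.24-fold), with a median of 0.15 (adjusted p = 0.0139, and adjusted p = 0.197 with an estimated correlation). Among the 16 without the saturated Sftpc 8 rose (median 0.18, adjusted p = 0.00789, and adjusted p = 0.167 with an estimated correlation). Of 7 alveolar type 1 genes 2 fell, Cyp2b10 (1.15-fold) and Aqp5 (1.14-fold), with a median of -0.13 (adjusted p = 0.0458, and adjusted p = 0.319 with an estimated correlation). Both gene calls ended when any WT or tg/wt array was left out, and the list's call ended without WT 1 (0.0830), WT 2 (0.0519) or tg/wt 1 (0.158), with quantile normalization (0.15) and with the mean of a gene's probes (0.0556). Airway epithelium genes fell in 10 of 13 cases, including Reg3g (3.26-fold) and Bpifa1 (2.39-fold), with a median of -0.56 (adjusted p = 1.33e-07, and adjusted p = 0.0962 with an estimated correlation). Of 16 endothelial genes 5 fell (6 adjusted over the list alone), such as S1pr1 (1.21-fold), and Tie1 rose by 0.18 and Emcn by 0.16 on the log2 scale (median -0.14, adjusted p = 0.143). Fibroblast and matrix genes rose in 8 of 18 cases, led by Col3a1 (1.49-fold), with a median of 0.15 (adjusted p = 0.00428, and adjusted p = 0.178 with an estimated correlation). Th2 genes showed no common direction, with Il10 called higher, though not well above background in either group, and Il4 (at least 1.20-fold) and Il24 (at least 1.14-fold) lower, or 3 lower adjusted over the list alone (median 0.09, adjusted p = 0.991). Of the Th17 members, Ccr6 was 1.35-fold higher and Ccl20 did not pass.

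All 9 heart muscle genes fell in tg/wt, with Nppa 5.12-fold and Mybpc3 2.94-fold lower (median -1.01, adjusted p = 2.02e-09, and adjusted p = 0.0757 with an estimated correlation). Fat genes fell in 4 of 6 cases, including Cidea (1.98-fold) and Cfd (1.65-fold), with a median of -0.66 (adjusted p = 0.00240, and adjusted p = 0.226 with an estimated correlation). Of 5 erythroid genes 3 fell, led by Slc4a1 (1.84-fold), with a median of -0.28 (adjusted p = 0.0317, and adjusted p = 0.178 with an estimated correlation). The call of that list ended with quantile normalization (0.0520) and with the mean of a gene's probes (0.0556). Skeletal muscle genes went both ways, with Myh4 (2.41-fold), Atp2a1 (1.51-fold) and Ckm (2.27-fold) lower and Tnnt3 (1.64-fold) and Tnni2 (log2 difference 0.33) higher, or 4 lower adjusted over the list alone (median -0.21, adjusted p = 0.274). Immediate early and heat shock genes fell in 10 of 13 cases, among them Fos (1.91-fold) and Hsph1 (1.87-fold), with a median of -0.29 (adjusted p = 2.13e-05, and adjusted p = 0.178 with an estimated correlation). Of 10 clock output genes Per3 (1.91-fold) and Per2 (1.27-fold) rose, 3 adjusted over the list alone, and the list did not pass (median 0.02, adjusted p = 0.143). Of the thymus members, Dntt (1.54-fold) and Cd1d1 (1.23-fold) were higher and Ccl25 (1.32-fold) lower.

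Leaving out an array of either group lowered the counts in tg/wt against WT, to 802 higher and 595 lower without WT 1, 761 and 711 without WT 2, 919 and 888 without tg/wt 1, and 746 and 718 without tg/wt 2. With no filter on dim probes 1208 genes were lower, while normexp on the median signal left 0 higher and 1 lower, ended the calls of the B cell, NK, proliferation, type I interferon, GM-CSF, immediate early, erythroid and alveolar type 1 lists, turned the sign of the NK (median -0.24), proliferation (-0.24), alveolar type 1 (0.16) and erythroid (0.0277) medians, and shrank those of the Th1 (0.0213) and T cell (0.0891) lists.

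**Figure D2:**
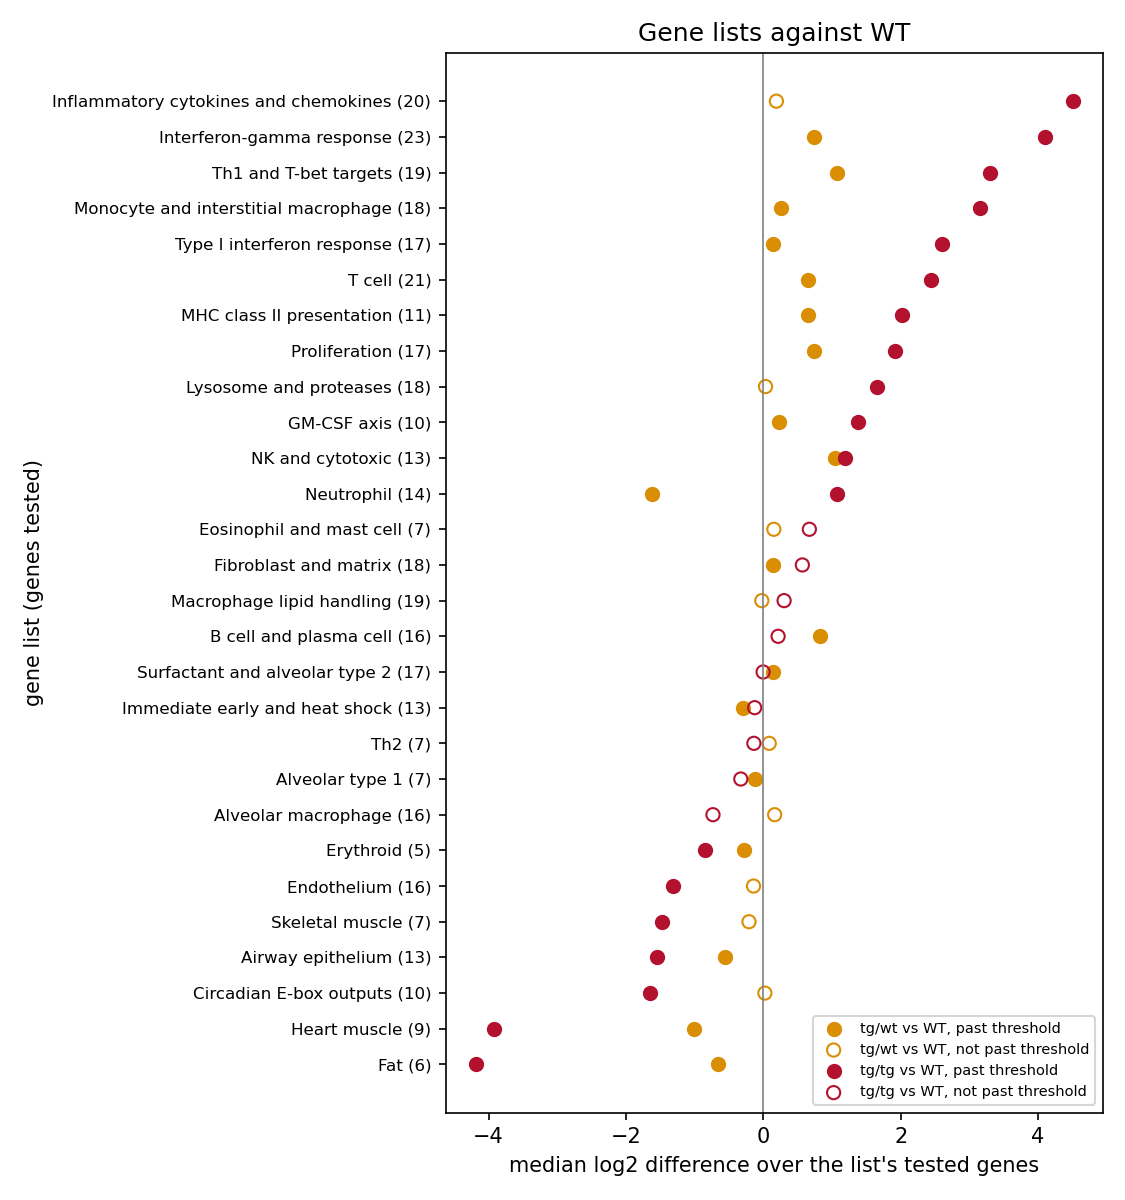
Median log2 difference from WT of each gene list in tg/wt (orange) and tg/tg (red), as fitted, with the number of genes tested in brackets; filled points passed the camera test with the preset correlation. Medians in tg/tg range from -4.19 for fat genes to 4.50 for inflammatory cytokines and chemokines, and the neutrophil list lies at -1.63 in tg/wt and 1.07 in tg/tg.

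The comparison of tg/tg with tg/wt asks what changes between the intermediate and the highest Tbx21 level. Interferon response genes and inflammatory chemokine genes were higher in tg/tg, along with neutrophil, monocyte and interstitial macrophage, and lysosome genes, and endothelial, heart muscle, fat and clock output genes were lower. None of these lists passes with the correlation estimated, where the smallest is adjusted p = 0.0653 with an estimated correlation. Saa3 was 318-fold higher (log2 difference 8.31, SE 0.0540), Ubd 174-fold (7.44, SE 0.0451), Cxcl5 at least 51.8-fold, Npy at least 47.4-fold and Cxcl3 at least 39.1-fold. Slc7a10 was at least 131-fold lower, Fabp1 at least 105-fold, Cyp1a1 at least 15.5-fold, Cidec 81.9-fold (log2 difference -6.36, SE 0.0439) and Bex2 80.5-fold. Of the 12968 genes, 4404 were higher and 5217 lower, or 74.2% (limma, Benjamini-Hochberg threshold 0.05).

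All 23 interferon-gamma response genes were higher in tg/tg than in tg/wt, including Cxcl9 (29.8-fold) and Ido1 (12.3-fold), with a median of 3.098, or 2.94 with bounds (camera adjusted p = 7.52e-12, and adjusted p = 0.0653 with an estimated correlation). Of 19 Th1 and T-bet targets, Tbx21 itself included, 17 were higher (18 adjusted over the list alone), with Ccl3 31.5-fold, Ccl4 18.1-fold and Ifng 15.7-fold, and Hopx fell by 1.54 (median 1.98, adjusted p = 1.44e-07, and adjusted p = 0.0653 with an estimated correlation). All 17 type I interferon genes rose, led by Oas3 (33.0-fold), with a median of 2.32 (adjusted p = 9.41e-09, and adjusted p = 0.0716 with an estimated correlation). Of 20 inflammatory cytokine and chemokine genes 18 rose, including Ccl2 (61.8-fold), Cxcl1 (47.5-fold) and Il6 (at least 31.8-fold), and Ccl17 fell by 2.88 and Il18 by 0.22 (median 4.15, or 3.99 with bounds, adjusted p = 7.80e-08, and adjusted p = 0.0653 with an estimated correlation). MHC class II genes rose in 10 of 11 cases, led by Ctss (7.57-fold), and H2-Ob fell by 1.42 (median 1.41, adjusted p = 1.39e-04, and adjusted p = 0.104 with an estimated correlation). Of 21 T cell genes 19 rose, including Icos (7.07-fold) and Cd6 (6.89-fold), and Ccr7 fell by 2.09 and Tcf7 by 0.55 (median 1.76, or 1.65 with bounds, adjusted p = 9.56e-07, and adjusted p = 0.0826 with an estimated correlation). NK and cytotoxic genes rose in 8 of 13 cases, with Gzmk 15.7-fold higher, and Ncr1 fell by 1.52 and Klra9 by 0.49 (median 0.43, adjusted p = 0.0131, and adjusted p = 0.126 with an estimated correlation). Proliferation genes rose in 16 of 17 cases, such as Ccnb1 (3.15-fold), with a median of 1.20 (adjusted p = 1.87e-06, and adjusted p = 0.0716 with an estimated correlation). B cell and plasma cell genes went both ways, 6 of 16 higher, led by Jchain (4.43-fold), and 9 lower, led by Blk (at least 2.27-fold) and Cr2 (at least 3.16-fold) (median -0.36, adjusted p = 0.566). Where no other count is given, the counts adjusted over the list alone were the same.

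All 14 neutrophil genes were higher in tg/tg than in tg/wt, with Lcn2 27.0-fold, Mpo 19.6-fold and Camp at least 14.3-fold (median 3.02, or 2.88 with bounds, adjusted p = 9.54e-08, and adjusted p = 0.0826 with an estimated correlation). Of 18 monocyte and interstitial macrophage genes 15 rose (16 adjusted over the list alone), including Gpnmb (18.4-fold) and Trem2 (14.7-fold), with a median of 3.001 (adjusted p = 7.80e-08, and adjusted p = 0.0716 with an estimated correlation). Lysosome and protease genes rose in 17 of 18 cases, led by Mmp12 (at least 60.5-fold) and Ctsk (6.32-fold), with a median of 1.53 (adjusted p = 9.54e-08, and adjusted p = 0.0653 with an estimated correlation). In the GM-CSF axis 7 of 10 rose, such as Csf2rb2 (9.64-fold), and Pparg fell by 1.16 and Stat5b by 0.18 (median 1.09, adjusted p = 0.0272, and adjusted p = 0.195 with an estimated correlation). Alveolar macrophage genes were higher in 6 of 16 cases and lower in 9, with Krt79 (34.8-fold) and Ear1 (14.1-fold) among the latter (median -0.53, adjusted p = 0.425). Lipid handling genes were higher in 11 of 19 cases, led by Msr1 (61.5-fold), and lower in 6, including Pltp (3.24-fold) (median 0.75, adjusted p = 0.164). Of 7 eosinophil and mast cell genes 4 rose, including Prg2 (9.37-fold), and Kit fell 3.01-fold (median 0.47, adjusted p = 0.107). Th2 genes divided again, with Il24 (at least 7.45-fold) and Il10 (at least 5.23-fold) higher and 3 lower, including Gata3 (2.19-fold) (median -0.19, or -0.11 with bounds, mean 0.54, adjusted p = 0.945). Of the Th17 members Ccl20 rose 2.88-fold and Ccr6 fell 2.001-fold. Where no other count is given, the counts adjusted over the list alone were the same.

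All 16 endothelial genes were lower in tg/tg than in tg/wt, including Kdr (3.36-fold) and Tek (3.34-fold), with a median of -1.14 (adjusted p = 6.62e-06, and adjusted p = 0.0716 with an estimated correlation). Airway epithelium genes fell in 11 of 13 cases, led by Bpifa1 (7.63-fold), and Reg3g rose by 0.83 on the log2 scale (median -0.95, adjusted p = 0.00414, and adjusted p = 0.231 with an estimated correlation). Surfactant and alveolar type 2 genes went both ways, 5 of 17 higher, such as Ctsh (2.91-fold) and Sftpd (2.01-fold), and 8 lower, such as Lgi3 (2.44-fold) (median -0.00, mean 0.02, adjusted p = 0.945, and median -0.07, adjusted p = 0.872 without the saturated Sftpc). Of 7 alveolar type 1 genes Pdpn rose 2.46-fold and 4 fell, including Cyp2b10 (2.71-fold) (median -0.26, adjusted p = 0.515). Fibroblast and matrix genes were higher in 8 of 18 cases, led by Timp1 (20.1-fold), and lower in 8, including Lum (3.01-fold) (median 0.11, adjusted p = 0.515). All 9 heart muscle genes fell, with Nppa 16.4-fold and Myl7 11.5-fold lower (median -3.05, adjusted p = 1.82e-05, and adjusted p = 0.120 with an estimated correlation). All 6 fat genes fell too, among them Cfd (33.0-fold), with a median of -3.42, or -2.50 with bounds (adjusted p = 0.00323, and adjusted p = 0.232 with an estimated correlation). Skeletal muscle genes fell in 6 of 7 cases, including Myh4 (6.59-fold), with a median of -1.46 (adjusted p = 0.0110, and adjusted p = 0.126 with an estimated correlation). All 10 clock output genes fell, led by Dbp (8.15-fold) and Hlf (5.43-fold), with a median of -1.73 (adjusted p = 5.31e-05, and adjusted p = 0.0716 with an estimated correlation). Erythroid genes fell in 4 of 5 cases, with Hba-a1 1.49-fold lower (median -0.22, adjusted p = 0.105). Immediate early and heat shock genes went both ways, 7 of 13 higher, such as Fos (3.09-fold), and 4 lower (median 0.18, adjusted p = 0.368). Of the thymus members Cd1d1 rose 1.98-fold and Dntt 1.22-fold, and Ccl25 fell 1.24-fold. The counts adjusted over the list alone were the same for these lists. With normexp on the median signal 1437 genes were higher and 1873 lower.

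In all 3 comparisons the members that went against their list (such as Hopx, H2-Ob, Ccr7, Tcf7, Ncr1, Klra9, Ccl17, Il18, Pparg, Stat5b, Il18r1, Jchain in tg/wt, Spp1, Cd14, Tie1, Emcn, Tnni2, Il1rl1 and Reg3g in tg/tg against tg/wt) were chosen after their values were seen. Testing every probe on its own, 9049 probes were higher and 10039 lower in tg/tg against WT. In tg/wt against WT 2808 were higher. In tg/tg against tg/wt 8807 were higher and 10046 lower, because more features were tested. In a check of genes with several tested probes, 4247 in all, probes of 303 genes were called in opposite directions in tg/tg against WT, of 6 in tg/wt against WT and of 295 in tg/tg against tg/wt, and no gene named by the rule fixed in advance was among these. Other probes of named genes gave smaller or larger values, at a log2 difference of 3.76 for Saa1, 3.29 for Oas3, -2.34 for Sln, 2.84 for Cd6 and 4.12 for Il24 in tg/tg against WT, and of 3.69 for Oas3 and 1.11 for Cd6, which did not pass, in tg/tg against tg/wt. In tg/wt against WT a further probe did not pass for Etv5 (0.11), Slc34a2 (0.26), Muc1 (0.51), Mcpt4 (-0.20), Per2 (0.31), Ccnb1 (0.62), Ccl25 (-0.17), Atp2a1 (-1.08), Fabp4 (-0.65), Il24 (0.13) and Rsad2 (-0.25 and -0.19), whose own probe was at adjusted p = 0.0503 over all probes.

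The differences of tg/tg and of tg/wt from WT share the WT arrays. Across the 12968 genes they correlated at Pearson r = 0.417 and Spearman's rho = 0.338, while unchanged groups simulated against the same arrays gave a mean r of 0.496 over 100 draws. The covariance was 0.180 against a simulated 0.00965, a difference of 0.170. With a different WT array in each difference r was 0.362 both ways round. Of the genes higher in tg/wt, 1086 were also higher in tg/tg, where independent lists would share 586, and of those lower in tg/wt 1204 were also lower in tg/tg, where independent lists would share 771. In opposite directions, 439 genes were higher in tg/tg and lower in tg/wt, against 639 for independent lists, and 379 lower in tg/tg and higher in tg/wt, against 707. The 2 WT arrays cannot be divided into groups of 2, so part of the excess may come from the shared controls. Of 3108 genes called in both comparisons, 2290 went the same way, and 2030 of these had the larger fitted difference in tg/tg.

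**Figure D3:**
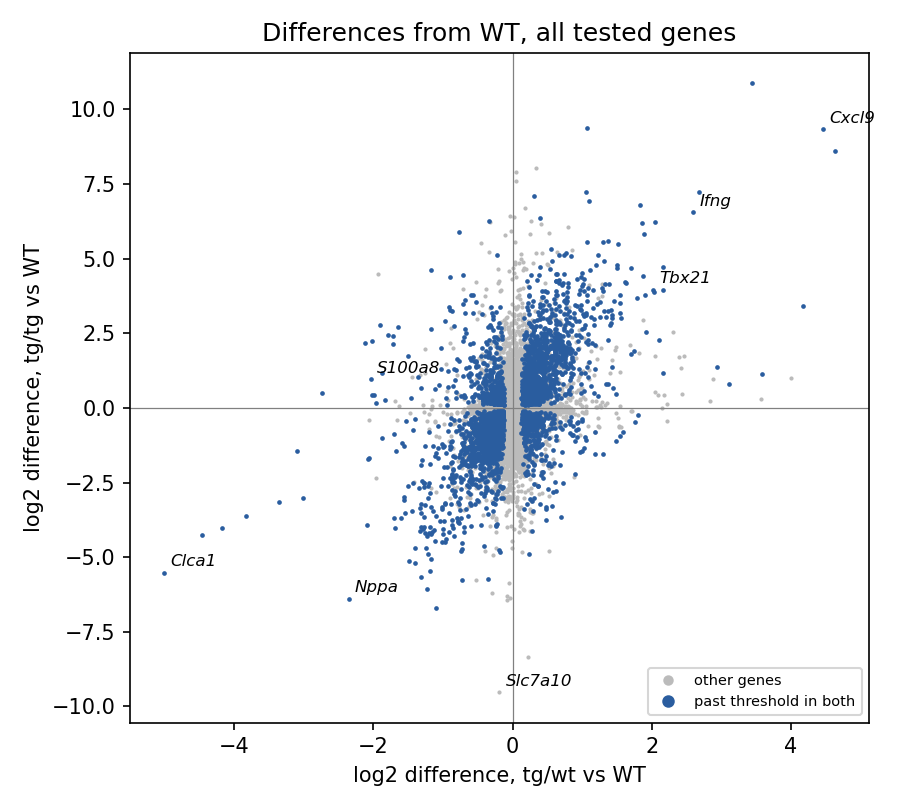
Fitted log2 difference from WT of each of the 12968 tested genes in tg/wt (horizontal axis) and tg/tg (vertical axis), with genes past the threshold in both comparisons in blue and other genes in grey; genes below background in a group are drawn at their fitted value. Tbx21, Ifng and Cxcl9 are higher in both genotypes, Clca1 and Nppa are lower in both, S100a8 is lower in tg/wt and higher in tg/tg, and Slc7a10 is lower in tg/tg.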

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

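Of the alternatives below, both normexp versions and the lists without the saturated Sftpc were chosen only after the data were seen. Among 369 named-gene results, alternatives other than normexp on the median signal kept direction and call in 4038 of 4121 cases and ended the call in 82, and leaving out an array kept 2083 of 2214 and ended 131, nearly all in tg/wt against WT. Lists without Sftpc gave the same counts of lists called. The intensity trend, the floor, the series values, quantile normalization and other scalings kept every count of genes within 1.5 times, and normexp with outlying backgrounds replaced gave 4145 higher and 5000 lower in tg/tg against WT, 1240 and 1460 in tg/wt against WT, and 4216 and 4793 in tg/tg against tg/wt. Signal over background limits the dimmest genes, whose folds are bounds. The replicate numbers of the labels do not pair the arrays (correlations of deviations 0.129, -0.0480 and -0.0458); with the replicate number as a block the counts were 4256 higher and 5191 lower, 1269 and 1345, and 4253 and 5110 in the order above, and 12 and 7, 12 and 6, and 12 and 6 lists; the list no longer called in tg/wt against WT was alveolar type 1 (adjusted p = 0.0538).

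Normexp on the median signal left 1779 genes higher and 2342 lower in tg/tg against WT, 0 and 1 in tg/wt against WT and 1437 and 1873 in tg/tg against tg/wt, moved the median of all genes in tg/tg against WT to -0.17, raised the correlation of the effects to 0.549 and ended the Tbx21 call in tg/wt against WT (1.79, adjusted p = 0.0586). Extreme local backgrounds on WT 1 and WT 2 lift the dim genes of those arrays in this version, and replacing them brought the counts closer to those without normexp, though not fully in tg/wt against WT, where 1152 of the 1732 genes called higher and 1340 of the 1887 called lower were shared. Of the 369 named-gene results it kept direction and call in 202, ended the call in 126 with the same sign, and gave the opposite sign, without passing, in 41. In tg/tg against WT these were Nos2 -0.14, Il10 -0.44, Il24 -0.16, Ccl20 -0.33, Ctla4 -0.90, Spi1 -0.0634, Ngp -0.23, Epx -1.12, Mcpt4 -0.31, Cenpe -0.92 and Dntt -0.71. In tg/wt against WT they were Gzmk -0.43, Fbxw14 -0.53, Mageb4 -0.88, Ccl3 -0.0584, H2-Ob -0.40, Il10 -1.66, Ccr6 -0.10, Icos -0.81, Blk -1.11, Siglecf -0.0513, Plet1 0.0759, Cx3cr1 -0.13, Olr1 -0.21, Etv5 -0.27, Csf2 -0.18, Cyp2b10 0.0634, Aqp5 0.16, Eng 0.0386, Cldn5 0.0915, Cma1 -0.22, Tnf -0.72, Cenpe -1.50, Ccnb1 -0.75, Aurkb -0.91, Alas2 0.0277, Hba-a1 0.0240, Tnnt3 -0.17, Dntt -0.97 and Per3 -0.17. In tg/tg against tg/wt, Il13, near background, was at 0.0525 and, with outlying backgrounds replaced, 0.0504.

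With no filter on dim probes 1208 genes were lower in tg/wt against WT and the correlation of the effects was 0.384; with probes well above background on all 6 arrays it was 0.446. The cause was not tested. Testing every probe on its own gave 9049 higher and 10039 lower in tg/tg against WT, 2808 higher in tg/wt against WT, and 8807 and 10046 in tg/tg against tg/wt, because more features were tested. Leaving out 1 array gave 746 to 1648 higher and 595 to 1824 lower in tg/wt against WT, with fewer arrays, and a correlation of 0.394 to 0.428; a lone array was assumed to vary like the other groups. With the correlation estimated per list 0 lists were called higher and 0 lower in every comparison, against 12 and 7, 12 and 7, and 12 and 6 with the preset one. This includes lists whose estimate lay below the preset, such as interferon-gamma response (-0.0252) and Th1 (-0.00448). A lost call therefore does not show that a list's genes move together. By fry, which tests a list on its own, 11 lists were lower in tg/wt against WT and 10 in tg/tg against tg/wt. In tg/tg against WT every list but immediate early and heat shock (adjusted p = 0.929) passed by fry. These include lists that camera did not call, such as B cell (1.55e-05), Th2 (0.00149), alveolar macrophage (8.14e-05) and surfactant (0.00690).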

Other observations

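Gene families, 25 of them with at least 5 tested genes, were looked at after the values of many members had been seen, and those printed first were picked for moving mostly in a single direction. In tg/tg against WT, 18 of 19 tested glutathione S-transferase genes, which encode detoxifying enzymes, fell and none rose, with Gsta2 14.9-fold, Gsta1 10.9-fold and Gsta3 7.44-fold lower (family median -1.19, and -1.20 to -0.90 over the other scalings and backgrounds). Of 22 cytochrome P450 family 2 genes 14 fell and 3 rose (median -1.27, range -1.34 to -0.84), with Cyp2a4 18.0-fold and Cyp2a5 16.3-fold lower. Proteasome subunit and assembly genes rose in 33 of 37 cases and fell in 0, by a small amount (median 0.40, range 0.37 to 0.64), while Psmb8 (log2 difference 2.49), Psmb9 (4.58-fold) and Psmb10 (2.74-fold), the subunits of the interferon-induced immunoproteasome, rose most. Of 8 Fc receptor genes 6 rose and 1 fell (median 3.17, range 3.11 to 3.32), led by Fcgr4 (25.2-fold), and of 8 toll-like receptor genes 6 rose and 1 fell (median 1.84, range 0.99 to 1.85), led by Tlr2 (9.38-fold). In tg/wt against WT 13 of the 19 glutathione S-transferase genes fell and 0 rose, by little (median -0.22, range -0.23 to -0.03). Some other families went both ways in tg/tg against WT: of 32 collagen genes 13 rose and 12 fell, of 18 C-type lectin genes 7 rose and 8 fell, and of 79 ribosomal protein genes 21 rose and 15 fell. Others moved mostly in a single direction, such as the cathepsin genes, of which 12 of 14 rose and 2 fell. In tg/wt against WT 2 of the 37 proteasome genes rose, 2 fell and 33 did not pass.

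Of the tests below, only the time-of-day test was chosen before its result was seen. The permutation tests shuffle genes as if they were independent, so their p-values do not allow for genes that move together. The genes that differ between tg/wt and WT could come from the slide or the scan, since tg/wt lies alone on its own. A slide effect alone would leave these differences unrelated to those of tg/tg from WT, which lie within slide 1. With a different WT array in each the correlation across genes was 0.362. Both WT arrays lie on slide 1 and are not stated to come from separate animals. Whatever they share enters both differences and can raise the correlation, so the test does not decide how far the slide is the cause. Whether the slide lowered the neutrophil list, whose median was -1.63, cannot be told apart from the genotype: slide and group coincide, and the list was picked for that fall. Less blood in the tissue as the whole cause of that fall would lower erythroid genes as far. Their median lay 1.35 above that of neutrophil genes (permutation p = 0.00886). Because the neutrophil list was picked for its fall and the erythroid median was itself lower (-0.28), this comparison does not decide the question. A slide effect, in general or on individual genes and lists, stays open. So do less blood, differences between individual animals, other handling, sampling of the tissue and a biological effect of the genotype.

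In tg/tg, endothelial and airway genes were lower than in WT. A lower share of all resident lung cells alone would lower alveolar type 2 genes alike, but the endothelial median lay 1.31 below theirs (difference -1.31, permutation p = 1e-05, the smallest that 100000 resamples can give, and 4e-05 without the saturated Sftpc). Airway genes were not tested in this way. The alveolar type 2 genes themselves went both ways, with 6 of 17 higher and 5 lower. If some rose for another reason, they would hide a shared fall, so the test does not decide this. Over 5 other scalings and backgrounds the endothelial median lay between -1.35 and -1.03, so the choice among these settings does not account for the fall. Some of these settings change only the background. The others set the arrays level by their own signal, although most genes differ between tg/tg and WT. A scaling error common to all settings was therefore not tested and stays open. A lower share of resident cells, a change in the cells themselves, unequal loss of cell types, and unequal sampling of large airways, heart muscle and fat may each contribute. They stay open, as does the biological effect of the genotype.

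In tg/tg, all 10 clock output genes were lower than in WT. A different time of day at sampling predicts higher Arntl, Npas2 and Clock, but Npas2 was not well above background on enough arrays to be tested, and the mean of 1.41 over the other genes rests on Arntl (2.66, 6.30-fold, adjusted p = 8.17e-06), with Clock at 0.17 (adjusted p = 0.0127). Because a gene named in advance is missing, and Arntl may also rise when its repressor Nr1d1 falls, which was not tested, the test leaves this open. Dilution by infiltrating cells alone would lower alveolar type 2 genes alike, and the clock median lay below theirs (difference -1.65, permutation p = 4e-05, and 9e-05 without the saturated Sftpc). The limit of these reference genes given above holds here too, so dilution stays open. A loss shared with endothelial genes is not decided by the difference from their median (-0.34, permutation p = 0.550). This loss, dilution, time of day and an effect of the genotype on the clock cannot be told apart here.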
